A study of Mus musculus with 4 samples.

How the data were processed

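Gene expression was measured on Affymetrix Mouse Genome arrays in basal cells sorted from the tail epidermis of CD-1 mice. The mice carried a tamoxifen-inducible Cre recombinase under the keratin 14 promoter (K14CREER) or under the involucrin promoter (InvCREER), with a YFP reporter that Cre switches on. Living YFP-positive cells with high surface alpha6 integrin and no surface CD34 were collected, per the labels' protocols. This gate takes basal cells and excludes CD34-positive follicle cells. It holds no marker that would exclude CD34-negative, alpha6-positive cells outside the interfollicular epidermis. There were 4 arrays, 2 per Cre line, and the labels do not say whether the 2 arrays of a line came from separate mice, so p-values measure the spread between these samples, which may be technical.

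The labels hold 2 limits of the design. The titles give 3.5 days after induction, whereas the treatment protocol gives 4 days. The protocol also gives 1 ug of tamoxifen for K14CREER and 10 ug for InvCREER, so that dose and Cre line cannot be told apart.

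The authors amplified and labelled 100 ng of total RNA per array with a 3' in vitro transcription kit, per the labels' protocols. Probe sets were summarised with RMA in Affymetrix Expression Console 1.1, per the submitters' processing notes. The deposited values are on a log2 scale, with array medians of 5.41 to 5.44 and a highest value of 14.2. Detection calls were not used here. RMA sets the arrays to a common distribution, so that a change in total RNA per cell does not show, and differences near the top of the scale are compressed. The precision is limited by the number of arrays.

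Of 45101 probe sets, 64 control probe sets were set aside. Probe sets were kept if their mean over the 4 arrays was at or above the median of the other 45037 probe sets, a log2 value of 5.42, which left 22519. Genes were named from the platform annotation, with symbols looked up by Entrez number in a RefSeq gene table of GRCm38.p6, used for names alone. Of the 45037 probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were unnamed here. No gene was named from a probe set with several symbols. The tested probe sets with 1 symbol covered 11270 genes, and each gene was represented by its probe set with the highest mean.

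InvCREER was compared with K14CREER with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), 2-sided, with no block. A probe set was called changed at a Benjamini-Hochberg adjusted p under 0.05 over the 22519 tested probe sets. Differences are InvCREER minus K14CREER in log2 units with the moderated standard error (SE). An exact permutation test of 2 against 2 arrays cannot give a 2-sided p under 0.333. A count without a variance model was therefore set beside it, of probe sets with both arrays of one line at least 1.5-fold above both of the other.

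Before the data were examined, 32 gene lists were fixed for keratinocyte adhesion, differentiation, cell cycle, signalling, stress, metabolism and other cell types. Of their 799 genes, 738 had a named probe set. The 30 lists with at least 4 tested genes, sex-linked genes aside, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera compares a list with the other genes. Each list was also tested with camera with an estimated correlation, camera on ranks, and fry, which asks whether the genes of a list move one way on balance. With an estimated correlation camera used the 2 residual degrees of freedom of the fit, so that a lost call need not reflect correlated genes. Members were counted over all probe sets and adjusted over the list alone.

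The genes named were fixed by rule before the data were examined. They were Krt14, Ivl, Itga6 and Cd34 as checks of the Cre lines and the sort, and the 12 genes higher and 12 genes lower with the largest called difference and no overlap between the lines. Up to 4 members per list were added, called members first, and any member where the text says which passed. Xist, Ddx3y, Eif2s3y, Kdm5d and Uty served as a sample check. Ddx3y had no named probe set.

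The test was tried on simulated data of the same 22519 probe sets. At a log2 change of 1, 2% of the changed probe sets were recovered, and at a log2 change of 2, 51%. Of 58 simulated calls, 5 were false. Over 20 simulations of the 30 lists without any change, 2 lists were called. Probe sets were simulated as independent, so that this rate does not cover lists whose genes move together. Alternatives covered the dim probe set filter, variance model, array weights, scaling, replicate block, each array left out in turn, threshold, unit of testing, probe set kind and set test. When 1 array is left out, the lone array of its line is assumed to vary like the other line. Figures were drawn with matplotlib 3.10.9.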

Results

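The series holds 4 expression arrays of basal cells sorted from tail epidermis, 2 from K14CREER mice and 2 from InvCREER mice. It permits 1 comparison: how the basal cells marked by the involucrin-driven Cre differ from those marked by the keratin 14-driven Cre. Array pairs of the same line correlated across tested probe sets at r = 0.969 for K14CREER and r = 0.967 for InvCREER, and pairs of different lines at 0.928 to 0.958. These correlations are across genes, which are not independent replicates. By the median absolute log2 difference the closest pair was K14CREER 2 and InvCREER 2, at 0.231. The same-line pairs were at 0.252 for K14CREER and 0.255 for InvCREER. No pair of arrays held identical values.

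In basal cells marked by InvCREER 8 of 18 tested spinous differentiation genes rose against cells marked by K14CREER, while Krt15, Lamb3 and Sparc fell. Camera called the spinous list. The call was lost with an estimated correlation (camera adjusted p = 0.295), a test that used 2 residual degrees of freedom. Dsc1, a desmosomal cadherin of differentiating epidermis, rose by 3.06 (SE 0.17) in log2 units. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 2.22 (SE 0.16). Krt15, a basal keratin, fell by 1.38 (SE 0.15), and Sparc, a matrix-binding glycoprotein, fell by 2.36 (SE 0.14). limma called 216 of 22519 probe sets (0.959%), 154 higher and 62 lower in InvCREER, with 2 arrays per line. All 216 had no overlap between the lines, and 206 differed at least 2-fold. They covered 166 genes, while 17 called probe sets were not listed in the annotation and 7 had several symbols. At an unadjusted p under 0.05 there were 3133 probe sets, 1477 higher and 1656 lower. Over all tested probe sets 42.0% had no overlap between the lines, against 33.3% by chance. The number of calls depended on single arrays: it was 82 without K14CREER 1, 143 without K14CREER 2, 499 without InvCREER 1 and 981 without InvCREER 2.

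The 12 genes with the largest called increases were led by Serpinb12. Serpinb12, a serine proteinase inhibitor, rose by 5.00 (SE 0.45, adjusted p = 0.0115 by limma), from 6.10 ± 0.70 to 11.10 ± 0.72 (SD, n = 2 per line). Elovl4, which elongates very long fatty acids for the epidermal barrier, rose by 3.91, and Acer1, an alkaline ceramidase, by 3.86. Krt84, a hair-type keratin, rose by 3.76. The thioesterase gene Olah rose by 4.21, Muc15 by 4.06, Sdr16c6 by 4.02 and Bpifc by 3.80. The fatty acid carrier gene Cd36 rose by 3.68, Wfdc17 by 3.67, the glutathione transferase gene Gsta2 by 3.48 and Serpina3a by 3.42. Adjusted p from limma for these 12 genes ran from 0.00451 to 0.0416. In 4 of them, Olah, Muc15, Cd36 and Serpina3a, the K14CREER mean lay under the filter value of 5.42, so that background limits the size of the increase and its rank. The size also differed between the InvCREER arrays. On InvCREER 1 and InvCREER 2, Cd36 was at 9.17 and 7.56, Sdr16c6 at 11.17 and 9.97, and Serpina3a at 8.70 and 7.49. Serpinb12, Muc15, Elovl4 and Bpifc were instead lower on InvCREER 1.

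**Figure D1:**
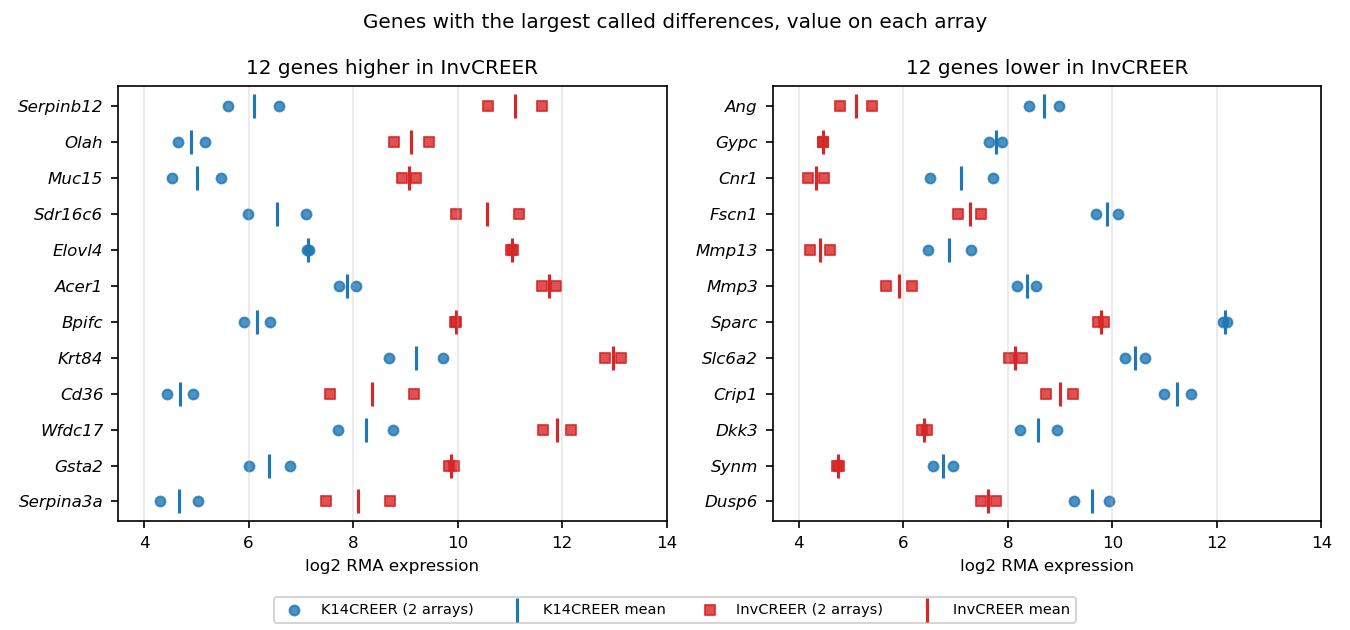
Log2 RMA expression (x axis) of the 12 genes higher and the 12 genes lower in InvCREER with the largest called differences. Points are single arrays and vertical ticks the mean of the 2 arrays of a line; in each of the 24 genes both arrays of one line lie above both of the other.

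The 12 genes with the largest called decreases were led by Ang. Ang fell by 3.61 on a probe set that can match several transcripts, and without such probe sets its difference was -0.78 (adjusted p = 0.311 by limma), against -2.26 with the mean of its probe sets (adjusted p = 0.00760 by limma). Gypc fell by 3.30, the cannabinoid receptor gene Cnr1 by 2.79 and Fscn1, an actin-bundling protein, by 2.62. With the mean of its probe sets Fscn1 was at -0.97 (adjusted p = 0.0506 by limma), and neither of its 2 other tested probe sets was called. The matrix metalloproteinase genes Mmp13 and Mmp3 fell by 2.48 and 2.44. Sparc fell from 12.15 ± 0.05 to 9.79 ± 0.09 (SD, n = 2 per line; adjusted p = 0.00612 by limma). The noradrenaline transporter gene Slc6a2 fell by 2.29, and was at -1.52 with the mean of its probe sets. Crip1 fell by 2.25 and Dkk3, a secreted Wnt modulator, by 2.19. The intermediate filament gene Synm fell by 2.01 and Dusp6, a phosphatase acting on ERK, by 1.98. In 5 of these 12, Ang, Gypc, Cnr1, Mmp13 and Synm, the InvCREER mean lay under 5.42, which limits the size of the decrease and its rank likewise. Of the 24 genes, 13 were called without any 1 of the 4 arrays too. Calls of 8 were lost without K14CREER 1 (Cd36, Serpina3a, Fscn1, Mmp13, Mmp3, Crip1, Synm and Dusp6), and of 5 without K14CREER 2 (Sdr16c6, Cd36, Mmp3, Slc6a2 and Dkk3). Without the variance trend calls of 8 of the 24 were lost, those of Sdr16c6, Cd36, Serpina3a, Cnr1, Mmp13, Crip1, Dkk3 and Dusp6, and of 19 of all 43 called genes named here. Without the filter on dim probe sets 6 of the 43 were lost (Actn1, Agrn, Notch3, Jag2, Xbp1 and Pmvk).

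The genes behind the Cre lines and the sort were read first as checks. Krt14 was 14.16 ± 0.02 in K14CREER and 13.83 ± 0.02 in InvCREER (SD, n = 2 per line; adjusted p = 0.0860 by limma), near the top of the scale. Itga6, the integrin of the gate, was 12.40 ± 0.02 and 11.69 ± 0.11 (adjusted p = 0.0564 by limma). Ivl, the involucrin gene itself, lay below the intensity filter, at 4.58 and 6.23 in K14CREER and 4.78 and 5.06 in InvCREER. Cd34, absent from the gate at the surface, also lay below it, at 6.07 on K14CREER 1 and 3.59 to 3.88 on the other arrays. Xist was 7.25 and 5.44 in K14CREER and 12.56 and 8.26 in InvCREER. The Y-linked gene Uty was 4.70 on InvCREER 1 and 7.19 to 7.85 on the other arrays, Kdm5d 5.04 against 7.01 to 8.09, and Eif2s3y 7.49 against 9.89 to 10.25.

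Genes that anchor basal cells to their basement membrane lay lower in InvCREER. All 12 tested basal keratin and hemidesmosome genes had lower means, by 0.83 on average, and none overlapped between the lines. This holds for the probe set with the highest mean of each gene. Of the 3 other Dst probe sets 1 had the same sign and 1 was called. The same sign was seen in 1 of the 2 other Plec and 2 of the 3 other Trp63 probe sets. Lamb3, a laminin chain of the epidermal basement membrane, fell by 1.77 and Krt15 by 1.38, while Itgb4 was at -1.33 (adjusted p = 0.0631 by limma). Of the 12, 2 were called over all probe sets and 11 adjusted over the list alone. Camera gave the list an adjusted p of 2.34e-11, and adjusted p = 0.295 with an estimated correlation. Of 18 integrin and focal adhesion genes, 1 fell, the actin cross-linker Actn1 (by 1.22), and 11 were lower and 2 higher when adjusted over the list alone. The list mean was -0.67 (camera adjusted p = 3.77e-07, adjusted p = 0.295 with an estimated correlation), with Itgb1 at -1.48 and Itga2 at -1.61. Of 19 basement membrane genes, Agrn fell by 1.43 and 11 were lower adjusted over the list alone. Their mean was -0.81 (camera adjusted p = 1.38e-07, adjusted p = 0.295 with an estimated correlation). Dermal fibroblast markers, of a cell type outside the gate, moved with them: all 10 had lower means, by 0.88 on average, and Sparc was the 1 called. Calls of Krt15 and Lamb3 were lost without K14CREER 1, and those of Actn1 and Agrn without either K14CREER array. Actn1 was at -0.86 with the mean of its probe sets (adjusted p = 0.0606 by limma).

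Genes of the suprabasal layers lay higher. All 18 tested spinous genes had higher means in InvCREER, by 1.28 on average. Of them 8 were called and 14 were higher adjusted over the list alone. This too holds for the probe set with the highest mean of each gene. The same sign was seen in 0 of the 2 other Skap2 and 1 of the 2 other Dsp probe sets. The transcription factor genes Grhl3 and Grhl1 rose by 2.78 and 1.87, Dsg1b and Dsg1a by 2.22 and 1.29, Sbsn by 1.97, and the spinous keratin genes Krt1 and Krt10 by 1.29 and 0.71. Camera gave this list an adjusted p of 2.06e-17, and adjusted p = 0.295 with an estimated correlation. Of 18 granular and cornified envelope genes all had higher means, by 1.38 on average, again on the probe set with the highest mean. Among them Elovl4 and Krt2 rose, by 3.91 and 1.55, and 14 were higher adjusted over the list alone. The 1 other tested Lor probe set had the opposite sign. Tgm1, the transglutaminase of the envelope, was at 2.14 (adjusted p = 0.0558 by limma) and Sprr1b at 3.27 (adjusted p = 0.0608 by limma). The list had a camera adjusted p of 2.67e-14, and adjusted p = 0.295 with an estimated correlation. The call of Dsg1b was lost without either K14CREER array and that of Krt2 without K14CREER 1. Krt84 and Krt36, at 3.76 and 3.30, were the 2 called among 6 hair-type keratins. The mean of those 6 corresponded to 2.29-fold and their median was 0.25 in log2 units, with a camera adjusted p of 0.0156 and adjusted p = 0.415 with an estimated correlation. The call of this list was lost on ranks (adjusted p = 0.237) and without the filter on dim probe sets (adjusted p = 0.0839).

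**Figure D2:**
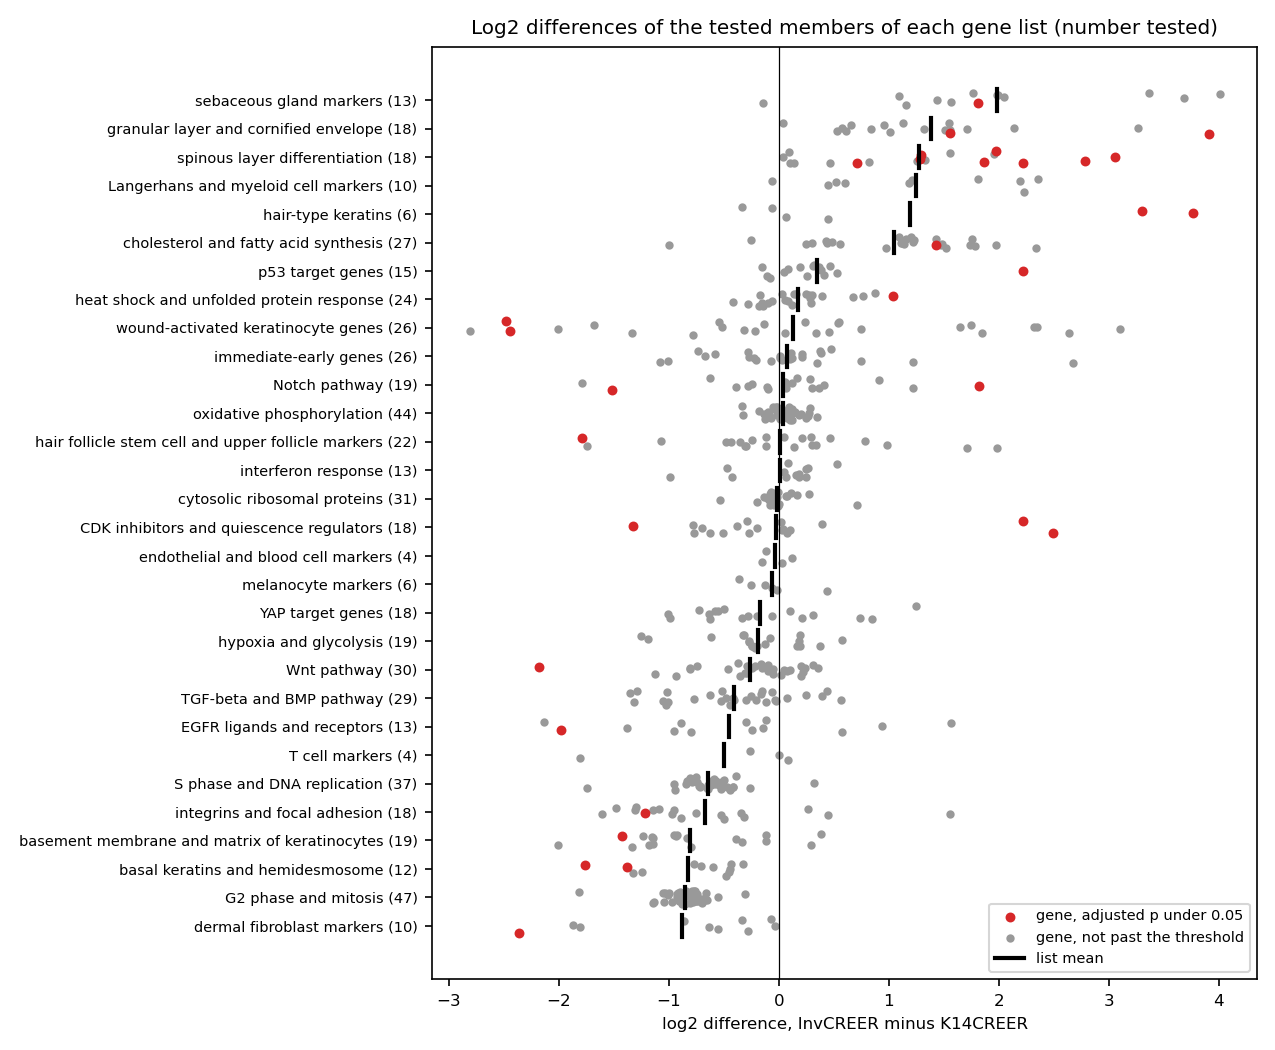
Log2 difference, InvCREER minus K14CREER (x axis), of each tested member of the 30 tested gene lists, 1 row per list with the number of members. Red points passed an adjusted p under 0.05 over all probe sets, grey points did not, and black bars are list means, which run from -0.88 for dermal fibroblast markers to 1.98 for sebaceous gland markers.

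Cell cycle genes lay lower in InvCREER as lists, with no single gene called over the 22519 probe sets. All 47 mitosis genes had lower means, by 0.85 on average, and 45 did not overlap between the lines. Birc5, which encodes survivin, was at -1.82 (adjusted p = 0.0565 by limma), Aurkb at -1.15 and Ube2c at -1.14. Over all probe sets 0 of the 47 were called, and 37 were lower adjusted over the list alone. The camera adjusted p was 8.74e-21, and adjusted p = 0.503 with an estimated correlation. Of 37 S phase genes 36 had lower means, 0 were called and 5 were lower adjusted over the list alone. Their mean was -0.64, with Tk1 at -1.75 and Cdt1 at -0.95 (camera adjusted p = 2.54e-11, adjusted p = 0.557 with an estimated correlation). Without K14CREER 2 it was -0.39. Both lists also differed by array number. Number 1 minus number 2 was -0.50 in K14CREER and -0.34 in InvCREER for S phase, and -0.49 and -0.26 for mitosis. Between same-numbered arrays InvCREER lay lower, by means of -0.56 (number 1) and -0.72 (number 2) for S phase and -0.74 and -0.97 for mitosis. Birc5 and Tk1 lay close to the threshold and were called in 9 of 16 alternatives each, among them the stricter filter (adjusted p = 0.0206 for both by limma) and 1 probe set per gene (adjusted p = 0.0196 for both by limma). Among 18 CDK inhibitors and quiescence regulators Cdkn2b rose by 2.49 and Cdkn1a by 2.22, while Ccng2 fell by 1.32. That list had a mean of -0.03 and was not called (camera adjusted p = 0.457). The call of Ccng2 was lost without either K14CREER array.

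The mean of 29 TGF-beta and BMP genes was -0.41, with 0 called and 8 lower adjusted over the list alone (camera adjusted p = 0.000119, adjusted p = 0.295 with an estimated correlation). Tgfbr3 was at -1.36 and Bmp4 at -1.29. Among 30 Wnt genes Dkk3 fell, and the list mean was -0.27 (camera adjusted p = 0.0264, adjusted p = 0.557 with an estimated correlation). The Wnt call was lost without K14CREER 1 (adjusted p = 0.0924), without InvCREER 2 (mean -0.18, adjusted p = 0.335), on ranks and at the stricter filter. Among 19 Notch genes the receptor gene Notch3 rose by 1.82 and the ligand gene Jag2 fell by 1.52, both calls being lost without either K14CREER array. The Notch list was not called (camera adjusted p = 0.633). Dusp6 fell among 13 EGFR pathway genes, whose mean was -0.45 (camera adjusted p = 0.113). That list was called without K14CREER 2 (adjusted p = 0.000327) and without InvCREER 1 (adjusted p = 0.00561), and at the stricter filter (adjusted p = 0.0430). The 15 p53 target genes had a mean of 0.35 (camera adjusted p = 0.00881, adjusted p = 0.373 with an estimated correlation), and Cdkn1a was the 1 called.

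Among wound-activated genes Mmp3 and Mmp13 fell and 24 of 26 were not called, with a list mean of 0.13 (camera adjusted p = 0.910). Adjusted over the list alone, 4 were higher, among them Krt16 at 2.35, and 5 were lower. The list depended on single arrays: its mean was 0.63 without K14CREER 1 (adjusted p = 0.00861) and -0.38 without K14CREER 2 (adjusted p = 0.0353), and 1.08 at the stricter filter on dim probe sets (adjusted p = 0.000349). S100a8, a calprotectin gene, was 10.59 on K14CREER 1 and 7.53 on K14CREER 2. Xbp1, a transcription factor of the unfolded protein response, rose by 1.03 among 24 heat shock and unfolded protein genes (camera adjusted p = 0.0878), a call lost without either K14CREER array and without probe sets that can match several transcripts (1.00, adjusted p = 0.0890 by limma). Lists of immediate-early genes (mean 0.08), YAP targets (-0.17), hypoxia and glycolysis (-0.19), oxidative phosphorylation (0.03), ribosomal proteins (-0.02) and interferon response (0.01) were not called. Without K14CREER 1 the immediate-early list was called, and without InvCREER 1 the YAP list. The hypoxia list was called without K14CREER 2 (adjusted p = 0.00641), without the filter on dim probe sets (adjusted p = 0.0414), at the stricter filter (adjusted p = 0.0430) and without probe sets that can match several transcripts (adjusted p = 0.0398). The heat shock list was called without K14CREER 1 (adjusted p = 0.00719) and without the filter (adjusted p = 0.0470).

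Lipid synthesis genes lay higher in InvCREER. Of 27 cholesterol and fatty acid synthesis genes 25 had higher means, by 1.05 over the list. Pmvk, a kinase of the mevalonate pathway, rose by 1.43, a call lost without either K14CREER array or without InvCREER 1, and Elovl6 was at 2.34 and Mvd at 1.97. Over all probe sets 1 was called, and 15 were higher and 1 lower adjusted over the list alone (camera adjusted p = 2.54e-11, adjusted p = 0.373 with an estimated correlation). The sebaceous gland markers, of cells that the gate is not shown to exclude, moved with this list. Their mean was 7.93 and 7.50 in K14CREER, 10.46 on InvCREER 1 and 8.93 on InvCREER 2. InvCREER 1 also had the highest log2 ratio of 3' to 5' probe sets, a sign of RNA quality, with 1.24 for Actb against 0.68 to 0.94 on the other arrays. Dgat2 rose by 1.81, a call lost without either K14CREER array, while Far2 was at 4.01 (adjusted p = 0.0649 by limma) and Cidea at 3.69. Of 13 markers 1 was called and 10 were higher adjusted over the list alone (camera adjusted p = 2.53e-09, adjusted p = 0.509 with an estimated correlation). Without InvCREER 1 the difference of the list was 1.21, against 1.98 with it.

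Other cell types were read from marker lists. Langerhans and myeloid markers had a mean of 5.88 and 5.65 in K14CREER, 7.63 on InvCREER 1 and 6.39 on InvCREER 2. Of 10, 0 were called and 5 were higher adjusted over the list alone, with H2-Aa at 2.36 and Ctss at 2.23 (camera adjusted p = 4.09e-05, adjusted p = 0.557 with an estimated correlation). The difference of that list was 0.63 without InvCREER 1 and 0.82 without the filter on dim probe sets, against 1.25. The dermal fibroblast markers, at -0.88, and at -0.54 without the filter on dim probe sets, had Sparc called among 10 and 4 lower adjusted over the list alone (camera adjusted p = 0.000119, adjusted p = 0.373 with an estimated correlation). Lgr6, a marker of upper follicle stem cells, fell by 1.79 among 22 follicle markers, a call lost without either K14CREER array. The follicle list was not called, its mean of 0.01 and median of -0.03 differing in sign. Melanocyte (-0.06), T cell (-0.50) and endothelial and blood (-0.03) lists were not called. Only 3 Merkel cell markers were tested, and Krt8 was 7.44 on K14CREER 1 and 5.08 to 5.34 on the other arrays.

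**Figure D3:**
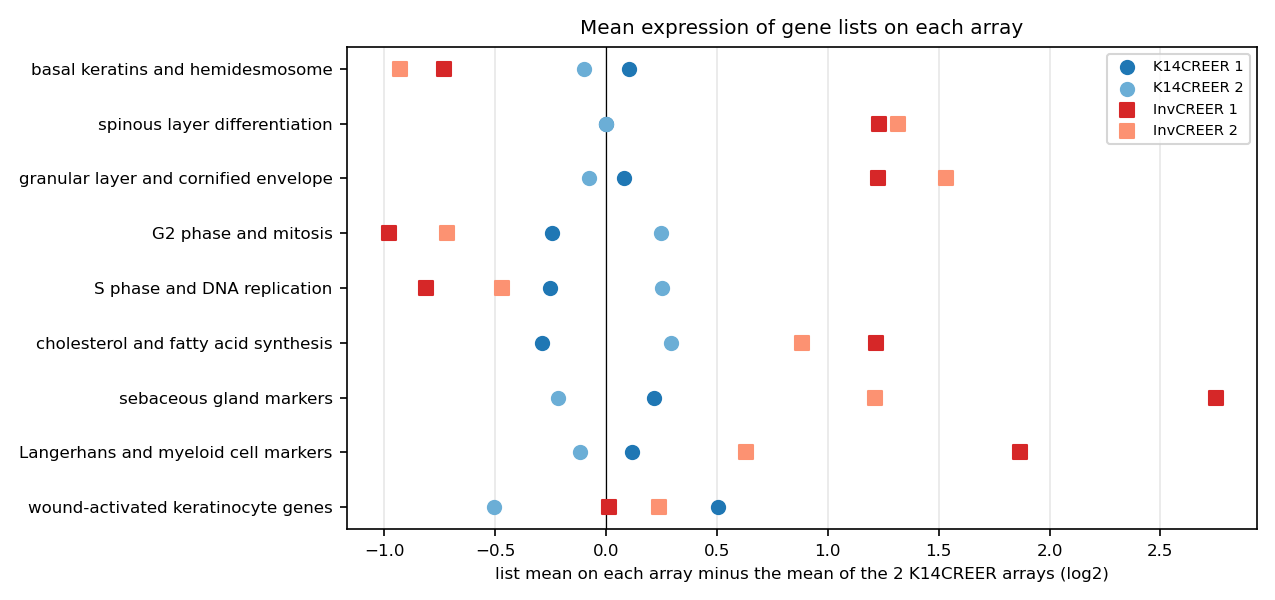
Mean log2 expression of 9 gene lists on each of the 4 arrays, relative to the mean of the 2 K14CREER arrays (x axis, log2). Sebaceous markers had a mean of 10.46 on InvCREER 1 and 8.93 on InvCREER 2, while spinous genes were at 11.49 and 11.58.

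Across the 30 tested lists camera called 15, 7 higher and 8 lower in InvCREER. With an estimated correlation 0 were called, with adjusted p from 0.295 to 0.976, and fry called 3, the spinous, TGF-beta and BMP, and p53 target lists. Without a variance model, 696 probe sets were at least 1.5-fold higher and 677 at least 1.5-fold lower in both InvCREER arrays than in both K14CREER arrays, 1373 in all. Pairing the arrays by replicate number in place of line gave 394, and the crossed pairs gave 36.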

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

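All tests in this part were chosen after the results had been seen, except the 2 tests on further sebaceous and myeloid marker genes, which were listed with their bounds before the values of those genes were read.

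Several signals were set apart for a closer look. Xist reached 12.56 on InvCREER 1, above the 7.25 of the higher K14CREER array. Hybridization controls, which are added to the sample, were higher on the arrays numbered 1, by a median of 0.44 in K14CREER and 0.31 in InvCREER. The Cre probe sets among these controls could also read the Cre transgene of the mice. Below the intensity filter, 153 probe sets were at least 1.5-fold higher in both InvCREER arrays than in both K14CREER arrays. Of the called probe sets, 17 were not listed in the annotation. With 2 arrays per line no array could be tested as an outlier.

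The first pattern is that the sebaceous and the Langerhans and myeloid lists, with 1 of 13 and 0 of 10 genes called, had higher means in InvCREER and the highest on InvCREER 1, which also had the highest 3' to 5' ratio (Gapdh 0.74 against 0.05 to 0.33). In the fixed lists 10 of 11 sebaceous markers that no other list holds, and 8 of 10 Langerhans and myeloid markers, lay in the order InvCREER 1, InvCREER 2, both K14CREER arrays; this order is how the pattern was noticed and tests nothing. Of 16 further sebaceous genes, with 3 left out because their calls had been seen, 6 lay in that order (8.33% by chance), between the 20% set in advance as counting against sebaceous cells in the sort and the 50% set as counting for them, so that such cells cannot be told apart from a change in the basal cells. Of 13 further myeloid genes 2 did (15.4%), with 0 among the 5 lying more than 1 log2 unit above the filter. This is under the 20% set in advance as counting against Langerhans cells. It is so by less than the binomial SE at that bound (11.1 percentage points, worked out only after the result), so that Langerhans cells stay open. Whether the gate on alpha6 integrin and YFP removed them was not tested. The sex of the animals stays open. InvCREER 2 exceeded the higher K14CREER array by a median of 0.88 over the sebaceous markers (12 of 13 above), with Y-linked genes at the K14CREER level. Its Xist, at 8.26, also lay above both K14CREER arrays. InvCREER 1 had the highest Xist (12.56) and the lowest Uty (4.70, against 7.19 to 7.85), so that sex may be unbalanced between the lines. For the excess on InvCREER 1, 0 of the 2 Cre lines had 2 arrays of each sex. With 2 arrays per line this outcome was fixed by the design, so that sex could not be tested.

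The second pattern is the lower cell cycle lists in InvCREER. If it acted alone, dilution by cells other than keratinocytes would have put the median of the spinous list below 0. That median was 1.29, while that of the mitosis list was -0.83, so that dilution alone does not account for both lists. A separate rise of the spinous genes would hide dilution, which therefore stays open for the cell cycle lists. A larger share of differentiating keratinocytes in the InvCREER sort stays open: the basal list had a median 0.17 above that of the mitosis list, which just exceeded a first bound (the interquartile range of the mitosis list, 0.17) but not the wider one set after the value was seen, which adds the 0.81 of the basal list. Tamoxifen dose cannot be told apart from the Cre line, as 0 lines had both doses, and a difference between the cells the Cre lines mark stays open, untested.

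The third pattern is the difference in control transcripts between arrays numbered 1 and 2. All 18 hybridization-control probe sets were higher on number 1 in both lines, as processing shared by same-numbered arrays would give. They read a few transcripts spiked in together, so that they are not 18 independent observations. With 1 array of each number per line, the lines could also share a direction by accident, so that shared processing stays open. Between the lines the median of these controls differed by 0.04, whereas all 24 poly-A controls were lower in InvCREER, by a median of -0.23. No biological explanation was tested.

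limma called 216 probe sets between the lines and at most 0 in the other ways to pair the 4 arrays. Only 1 of the 3 splits gave as many, and 3 splits are too few for a share under 0.05.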

How the results depend on the processing

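One alternative, leaving out the sebaceous and Langerhans marker genes (217 calls), was chosen after seeing the data. No direction changed among the 24 genes with the largest differences. The number of changed probe sets was within 1.5 times 216 without the dim probe set filter, with a robust fit and with median or quantile scaling. It stayed so without probe sets matching several transcripts. Quantile scaling raised the lower calls from 62 to 103. Array weights gave 216 as well, but both arrays of a line got the same weight, so that this fit could not set them apart. The number of changed probe sets was 405 (190 lower) at the stricter filter and 122 (96 higher, 26 lower) without the variance trend. It was 692 (379, 313) at an adjusted p under 0.1, 551 (302, 249) with 1 probe set per gene and 450 (260, 190) with the mean of a gene's probe sets. Leaving out 1 array gave 82 to 981 calls, 69 to 656 higher and 13 to 325 lower; the lone array makes these fits weak in design. Most of the 216 calls were lost without either K14CREER array, whereas nearly all of them remained without either InvCREER array. The replicate numbers are not stated to pair arrays, and with 2 pairs they cannot be shown to: same-numbered arrays deviated with r = 0.38 across probe sets. The fit with a replicate block called 1390 (681 higher, 709 lower) and 15 lists, and in it Birc5, Tk1, Ube2c, Aurkb and Cdt1 passed (adjusted p from 0.00538 to 0.0246); over all alternatives adjusted p ran from 0.00309 to 0.156 for Birc5 and from 0.00380 to 0.160 for Tk1. With all 4 arrays the count of lists was 13 to 16, against 15 in the main fit. Exceptions were 0 with an estimated correlation and 3 by fry. The estimated correlation ran from -0.071, for the p53 targets, to 0.953, for the sebaceous list. Calls were also lost where it lay under the preset 0.01, as in the basement membrane list (-0.035). In the spinous list, whose call was lost too, it was 0.021. High correlation alone therefore does not account for the loss. With an estimated correlation camera used the 2 residual degrees of freedom of the fit, which limits what it can call. The wound-activated list, at 0.63 without K14CREER 1, turned to -0.38 without K14CREER 2; the cause was not tested. Counts without a variance model were 479 (302, 177) at 2-fold, 3557 (1683, 1874) at 1.2-fold and 2089 (1119 lower) for same-numbered differences in a paired count. Signal over background limits Ivl and Cd34, both below the filter.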

Other observations

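The 2 K14CREER arrays differed from each other in several genes with no call between the lines. K14CREER 1 had the highest values of Krt8 and Krt18, keratins of simple epithelia and Merkel cells, with Krt18 at 7.69 there and at most 4.40 elsewhere. The wound-related genes S100a9 and Krt6b were low on K14CREER 2, at 6.93 and 6.08, while K14CREER 1, at 9.60 and 9.20, lay near the InvCREER arrays (S100a9 at 9.36 and 10.85, Krt6b at 9.48 and 10.44). Cxcl1, a chemokine gene, was 10.52 on K14CREER 1, 6.98 on K14CREER 2 and 7.39 and 6.75 in InvCREER. Ptgs2 was 8.81 and 6.51 in K14CREER and 5.52 and 4.17 in InvCREER.

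The ratio of 3' to 5' probe sets, a sign of RNA integrity and amplification, was highest on InvCREER 1. For Actb it was 1.24 in log2 units there and 0.68 to 0.94 on the other arrays, and for Gapdh 0.74 against 0.05 to 0.33. The 24 poly-A controls, added before amplification, were lower in InvCREER by a median of -0.23.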
